A study of Mus musculus with 18 samples.

How the data were processed

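The series holds 18 arrays of islet RNA, 6 at each of 3 ages (10 days, 4 weeks and 12 weeks). Per the labels' protocols, islets were isolated by collagenase digestion, and 300 ng of total RNA from 1 female NOD mouse, labelled with Cy5, was hybridised against 300 ng from a pool of 6 age-matched female NOD.B10 mice, labelled with Cy3, on Agilent whole mouse genome arrays. No dye was swapped. The group and the replicate number of each array came from its labels, which give each array an individual mouse.

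Per the file headers, the authors extracted the spots with Agilent Feature Extraction 10.7.3.1 (protocol GE2_107_Sep09, array design 014868), with probes annotated on mm9 (NCBI37). The deposited scanner tables hold, per the file headers, the mean intensity and the local background intensity of each spot in red (NOD) and green (NOD.B10), with no normalization, and also processed intensities that Feature Extraction had background-subtracted, spatially detrended and dye-normalized. They also hold a log10 ratio of red over green that Feature Extraction computed from the processed signals, per the file headers. The deposited table of values holds the authors' log2 ratios of red over green processed signal, as a comparison with the scanner tables showed on all 18 arrays (40929 probes with a single spot, largest difference 3.1e-06), so that its scale and direction are known and its columns are not centred further, with medians between −0.26 and 0.15. It served as an alternative.

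The main values were computed from the mean and background intensities in R 4.3.3 with limma 3.58.1 and the R package data.table (version 1.17.8). Background was corrected with normexp (offset 50), and each array was normalized by loess within the array, with control spots and spots with outlier marks given a weight of 0, which left log2 ratios of NOD over NOD.B10. Of 43379 gene spots per array, those of 1 probe were averaged, giving 41174 probes. A probe entered if it was well above background in red or green on at least 3 of the 6 arrays of at least 1 age, which 25814 did. For each of the 18099 gene names the probe with the highest mean brightness was kept, and 5775 genes had more than 1 entering probe. Called probes of opposite sign were found for 451 genes at 10 days, 408 at 4 weeks and 221 at 12 weeks, among them Zfp871 at 4 weeks and H2-Aa and H2-K1 at 12 weeks. Of the gene names 13994 matched the reference gene table (GRCm38.p6, used for names only) through an accession, 902 through a symbol and 157 through a synonym, and 3046 were kept as the array gives them. Coordinates are those of the array's annotation on mm9. Iapp and Amy2 were not measured under those names.

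One limma model with a mean per age was fitted to all 18 arrays, so that the ages share an estimate of the spread (eBayes, prior degrees of freedom 2.89). The ratio of each age was tested against 0 and the 3 differences between ages were tested as contrasts, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and a 2-fold call also needed a log2 size of at least 1. Each pool is 1 control sample, so the tests leave out the spread of the control mice. Where a gene's signal in 1 strain was not well above background on every array of an age, its difference is given as a bound, the brighter channel's mean against, per array, the higher of the lowest signal well above background and the dim probe's own signal, on levels after loess and quantile normalization of the mean brightness. Without a dye swap these bounds are open to dye bias.

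Lists of marker and pathway genes were written before the data were examined, as were the design, the rule for named genes and the alternatives. The lists cover beta cell identity and secretion, other islet hormones, secretory granules, genes low in mature beta cells, islet autoantigens, acinar, duct, Reg family, endothelial, mesenchymal, Schwann, adipocyte and red blood cell genes, T, B, cytotoxic, dendritic, macrophage and neutrophil or mast cell genes, T cell regulation, lymphoid tissue organisation, chemokines, MHC, both interferon responses, endoplasmic reticulum stress, oxidative stress defence, oxidative phosphorylation, cell cycle, immediate early and heat shock, and circadian genes. These 31 lists were tested at 6 contrasts with camera (preset correlation 0.01) against all other genes, adjusted over the 186 tests, and again with an estimated correlation, and fry was run beside it. With the preset correlation 91 of the 186 were called, and with an estimated correlation 0 of these held, the lowest adjusted p being 0.436, and 18 of them had an unadjusted p under 0.05. The median, the mean and the camera test of a list differed in sign in 20 of the 186, of which 0 were called. For the list tests 36 missing gene values were filled. A list of sex-linked genes had 1 measured member and was not tested. Some lists share genes, so their calls are not independent. All autoantigens but Ica1 and Gad1 are also on the beta cell, granule or Reg lists. Dcn, Pdgfra and Cxcl12, low in mature beta cells, are also on the mesenchymal or chemokine lists.

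The text names, for each contrast, the 10 largest called differences in each direction that have a gene symbol (with the same sign on all 6 arrays for a single age), the 4 members with the smallest p of each list that camera called at an age, and a fixed set of islet, immune and exocrine genes. The values of 4 genes that this rule names are not reported here, and these genes stayed in the tests and in their lists. Relations between list means across the mice of an age were tested with exact permutations, 12 in all. Genes called in 1 direction at all 3 ages were set against chromosomes with Fisher's exact test, over 17895 genes with coordinates.

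The 18 arrays lie on 5 slides. Slide 2 holds 2 arrays each of 10 days and 4 weeks, and the other slides hold 1 age each. The main fit had no slide term. Among the alternatives, slide entered as a fixed block for the change from 10 days to 4 weeks and as a random block for all contrasts. The consensus correlation of the random block was −0.17, a negative value, so that it takes out no shared slide effect. For arrays depth has no count, and the number of arrays limits the precision. Median signals lay between 52.4 and 121 in red and between 37.5 and 78.7 in green, and 0 probes were saturated. Tested on simulated data with the same number of genes, the limma step recovered 78% of 100 genes changed by 0.5 on the log2 scale and 100% of those changed by 1 at 10 days, 84% and 91% at 4 weeks, 78% and 95% at 12 weeks, and 69% and 93% for the change from 4 to 12 weeks, with 9, 6, 10 and 8 false calls. The simulated noise was normal and independent between genes, few genes were changed, and no pool deviation or dye bias was put in. These false calls therefore do not give the rate of false calls in the real data.

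The alternatives were the processed signals, the deposited value table, a normexp offset of 16, median centring, scaling between arrays, no filter and a strict filter on dim probes, every probe on its own, the mean of a gene's probes, each age fitted alone, a variance trend with robust moderation, array weights, slide and replicate number as blocks, each array left out, a 1.5-fold threshold and an estimated correlation. Leaving out together the arrays that stand apart on a list of another cell type, the relation of the type I interferon list to the Reg family, and relations between lists within slides were added after seeing the data. The log10 ratios of the scanner tables were set beside the processed signals and not tested themselves, and no genome sequence was used here.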

Results

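Gene expression was measured in the islets of female NOD mice, a strain that develops autoimmune diabetes spontaneously, against NOD.B10 mice, a congenic strain with another major histocompatibility complex (MHC) that stays free of diabetes. Each of 18 arrays compared the islet RNA of 1 NOD mouse, labelled with Cy5, with a Cy3-labelled pool of islet RNA from 6 NOD.B10 mice of the same age, with 6 arrays at each of 3 ages, 10 days, 4 weeks and 12 weeks. The comparison addresses how islets of the diabetes-prone strain differ from those of the healthy strain before and during the time when immune cells enter the islets. All log2 values are NOD over NOD.B10, so that positive values mean a higher level in the NOD mouse. Between 49.1% and 62.9% of the probes were well above background in the NOD channel and between 39.3% and 59.8% in the pool channel, and the number of arrays limits the precision. No pair of arrays held identical values (0 of 153 pairs), and the highest correlation between any pair was 0.87. Over all probes the arrays correlated with each other by 0.40 to 0.87 at 10 days, 0.32 to 0.80 at 4 weeks and 0.67 to 0.87 at 12 weeks. Arrays of 10 days and 4 weeks correlated between −0.34 and 0.45, and the direction of every array was kept because the labels state both dyes. The spread between NOD mice enters the tests, while each age has 1 pool, whose own spread is left out. No dye swap was made, so that a gene-specific dye bias would stay in the ratios of a single age and would repeat across the ages.

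At 10 days the islets of NOD mice had higher levels of islet hormone and secretory granule transcripts than the NOD.B10 pool, and lower levels of stromal, endothelial, adipocyte and cell cycle transcripts. Ppy, which encodes pancreatic polypeptide, was 9.16-fold higher (log2 3.20 ± 0.72, mean ± SD, n = 6; adjusted p = 1.7e-06), and Gcg, which encodes glucagon, was higher by 2.21 ± 0.65 on the log2 scale (adjusted p = 3.7e-08). Sst (somatostatin) was higher by 1.91 ± 0.75, Ins2 by 1.83 ± 0.86 and Ins1 by 1.24 ± 0.93, the last 2 encoding insulin. Col1a1, a chain of type I collagen, had a log2 ratio of −3.13 ± 1.02 (adjusted p = 4.8e-08), and Igf2, a fetal growth factor, had −2.48 ± 0.30 (adjusted p = 1.2e-11). Each of these genes had the same sign in 6 of 6 arrays.

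Of the 25 measured genes of beta cell identity and secretion, 22 were higher at 10 days and 0 lower (22 and 0 adjusted over the list alone), with a median log2 ratio of 1.19. Among them were Slc30a8, the zinc transporter of insulin granules, at 1.83 ± 0.56, and the transcription factors Isl1 at 1.80 ± 0.54 and Pax6 at 1.67 ± 0.42. Mafa, which activates insulin transcription, had 0.43 ± 0.34 (adjusted p = 0.0031), with its pool signal well above background on 3 of 6 arrays. The pan-endocrine secretory granule list had 15 of 17 members higher and 2 lower (the same counts adjusted over the list alone), led by the granins and granule proteins Scg2 (2.28 ± 0.59), Resp18 (2.23 ± 0.48) and Chga (2.20 ± 0.64). Of the 14 other islet hormone genes and their regulators 9 were higher and 1 lower, and of 10 islet autoantigens 9 were higher and 1 lower. Both pairs of counts were the same adjusted over the list alone. Camera placed these 4 lists above all other genes. The adjusted p-values were 4.13e-08 for beta cell identity, 1.97e-06 for the granule list, 0.000522 for the hormones and 0.000213 for the autoantigens. None of these calls held when the correlation between genes was estimated from the data (adjusted p = 0.509 for each). All 4 list means lay above 0 in 6 of 6 arrays.

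Genes of mesenchymal and stellate cells were lower in the NOD islets at 10 days, 17 of 20 with 0 higher (17 and 0 adjusted over the list alone; camera adjusted p = 2.36e-07, adjusted p = 0.509 with an estimated correlation). Besides Col1a1 they included Col6a1 (−1.46 ± 0.44) and Bgn, a small matrix proteoglycan (−0.98 ± 0.22). Adamts2 (−2.71 ± 0.74), Col5a1 (−2.50 ± 0.57), Mfap2 (−2.42 ± 0.56) and Cd248 (−2.39 ± 0.79) were also among the 10 lowest genes. Of 18 endothelial genes 14 were lower and 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 4.06e-05, and adjusted p = 0.521 with an estimated correlation). Von Willebrand factor, Vwf, had −1.97 ± 0.86 and the junction protein Cdh5 −1.69 ± 0.48. The adipocyte list had 7 of 8 genes lower and 1 higher, also adjusted over the list alone (camera adjusted p = 3.3e-05, and adjusted p = 0.436 with an estimated correlation). Adiponectin, Adipoq, had −1.62 ± 0.24, with its NOD signal well above background on only 1 of 6 arrays. This adipocyte call ended with the strict filter on dim probes (adjusted p = 0.622). Of 29 cell cycle genes 24 were lower and 0 higher (25 and 0 adjusted over the list alone; camera adjusted p = 1.03e-07, and adjusted p = 0.509 with an estimated correlation). The mitotic activator Cdc20 had −1.48 ± 0.49. Genes kept low in mature beta cells had 14 of 19 members lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.000226, and adjusted p = 0.436 with an estimated correlation). Rest, a repressor of neuronal and endocrine genes, had −1.12 ± 0.30. Of 24 chemokine genes 8 were lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.0458, and adjusted p = 0.632 with an estimated correlation). The monocyte chemokine Ccl7 had −1.35 ± 0.80 and was not called under median centring (−0.63, adjusted p = 0.0749). The chemokine call was lost without 10-day replicate 3 (adjusted p = 0.0819), replicate 4 (0.075) or replicate 6 (0.069), and with scaling between arrays (0.0635).

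Lymphocyte lists were not called at 10 days. Under median centring the B cell (−0.495, adjusted p = 6.31e-05) and cytotoxic (−0.51, adjusted p = 0.00013) lists were called lower, as was the T cell list, whose median turned from 0.033 to −0.025 relative to all genes (adjusted p = 0.0347). Of 25 T cell genes 1 was higher and 3 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.958). Of 22 B cell and plasma cell genes 1 was higher and 6 lower (0 and 4 adjusted over the list alone; adjusted p = 0.0928). This list was also called lower with the processed signals (0.0205), the deposited values (0.0202), each age alone (0.0299) and slide as a random block (0.0443), without 10-day replicate 5 (0.0276) and without the arrays that stand apart (0.032). Cd3e, a chain of the T cell receptor complex, had −0.16 ± 0.20 (adjusted p = 0.098, negative in 5 of 6 arrays). The acinar cell list, of digestive enzymes and their regulators, had 4 of 28 genes higher and 6 lower (2 and 5 adjusted over the list alone; adjusted p = 0.519) and spread widely between mice, with a list mean of −0.13 ± 0.79. The Reg family, secreted proteins of stressed or regenerating exocrine and islet cells, had 4 of 6 genes lower (5 adjusted over the list alone) and was not called (adjusted p = 0.1), other than under median centring (−1.162, adjusted p = 0.00946) and with each age alone (0.00561).

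With limma, 9864 of 18099 genes were called at 10 days, 5178 higher and 4686 lower, and 717 of them passed the 2-fold threshold, 290 higher and 427 lower. Median centring of each array in place of loess put the median of the 18099 tested genes, called all genes here, at 0.378 at 10 days, −0.147 at 4 weeks and 0.501 at 12 weeks, against 0.011, −0.004 and 0.027 with loess. List values under median centring are given relative to that median, and values of single genes against 0. The centring itself used the median of all gene spots, dim ones included. By its construction it leaves in any trend of the ratio with brightness, which loess removes. Under it 87.6% of the called and 98.1% of the 2-fold genes at 10 days were higher, against 52.5% and 40.4% with loess. The scanner's processed signals called 2926 genes with a 2-fold difference at 10 days, 55.3% of them higher.

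**Figure D1:**
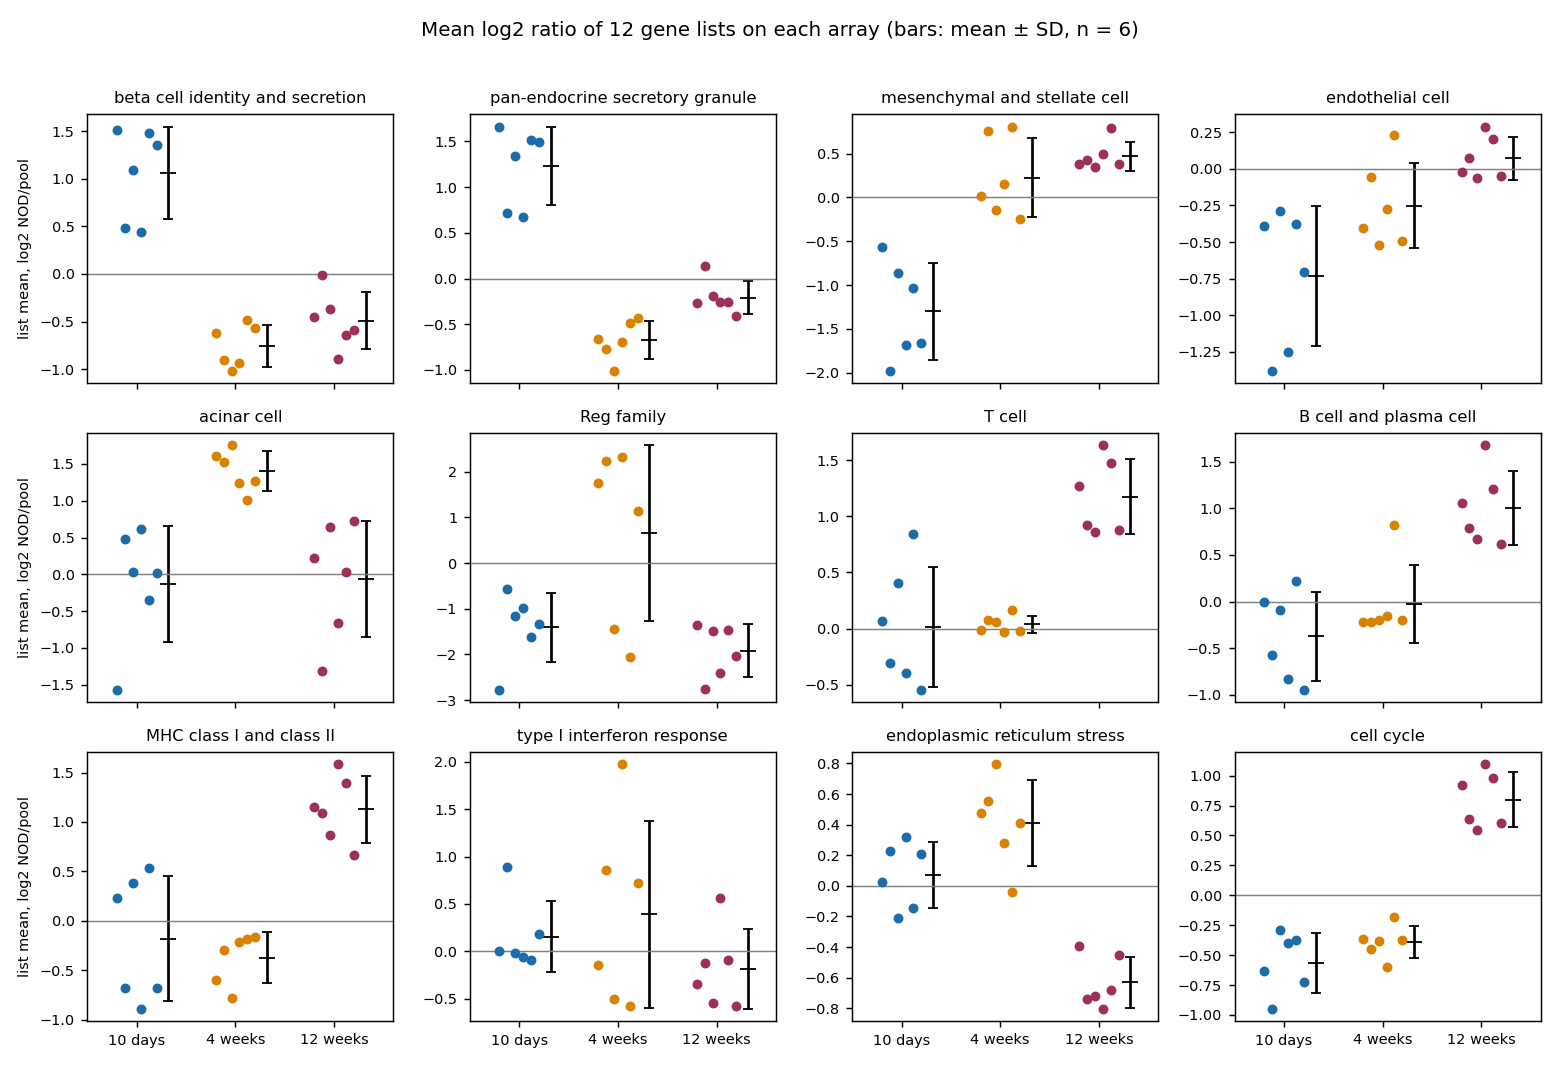
Mean log2 ratio of 12 gene lists on each array (dots, 6 per age) with the mean ± SD of the 6 arrays (bars). The beta cell list averaged 1.06 at 10 days and −0.76 at 4 weeks and the T cell list 1.17 at 12 weeks, and the granule and endoplasmic reticulum stress lists at 12 weeks have medians above that of all genes, not below it, when arrays are median centred.

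At 4 weeks the beta cell, granule and autoantigen lists were lower, opposite to 10 days, and the digestive enzymes of acinar cells were higher in the NOD islets. Pnliprp1, a pancreatic lipase-related protein, was higher by 2.05 ± 0.24 (mean ± SD, n = 6; adjusted p = 3.8e-06), the amylase gene Amy2a5 by 1.82 ± 0.19 (adjusted p = 2.5e-05) and chymotrypsin C, Ctrc, by 1.77 ± 0.31 (adjusted p = 3.2e-05). Ins1 had −1.49 ± 0.44 (adjusted p = 4.6e-05), and Pdyn, the opioid precursor prodynorphin, −2.67 ± 0.47 (adjusted p = 1e-08). The lowest gene was Glycam1, a mucin-like ligand of L-selectin on high endothelial venules, at −3.16 ± 0.81 (adjusted p = 3.9e-05). All of these genes had the same sign in 6 of 6 arrays.

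Of 28 acinar genes 27 were higher at 4 weeks and 0 lower (28 and 0 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 2.17e-09, and adjusted p = 0.509 with an estimated correlation). They included Ptf1a, the transcription factor that specifies acinar cells, at 1.72 ± 0.48, the bile salt lipase Cel at 1.69 ± 0.33 and trypsin, Prss2, at 1.28 ± 0.37. The acinar mean lay above 0 in 6 of 6 arrays. Psat1, an enzyme of serine synthesis, at 1.96 ± 0.33 and the glutaminase Gls2 at 1.85 ± 0.33 were also among the 10 highest genes. The endoplasmic reticulum stress list had 14 of 25 genes higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.00275, and adjusted p = 0.509 with an estimated correlation). Among them were the folding helpers Creld2 at 1.13 ± 0.28 and Dnajc3 at 0.83 ± 0.29.

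Genes of beta cell identity were lower at 4 weeks, 22 of 25 with 0 higher (22 and 0 adjusted over the list alone), with a median of −0.73 (camera adjusted p = 8.89e-07, and adjusted p = 0.509 with an estimated correlation). The transcription factors Nkx2-2 (−1.39 ± 0.21), Mafa (−0.88 ± 0.23) and Pdx1 (−0.81 ± 0.14) were among them, and so was the glucose transporter Slc2a2 (−1.11 ± 0.46). Ins2 had −0.72 ± 0.52 (adjusted p = 0.014, negative in 6 of 6 arrays), a call that was lost without 4-week replicate 3 (−0.54, adjusted p = 0.0737). Of 17 granule genes 15 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 1.46e-05, and adjusted p = 0.509 with an estimated correlation). Its members included the vesicle protein Vamp2 at −1.29 ± 0.13 and Ptprn, an autoantigen of type 1 diabetes, at −1.25 ± 0.21. The other hormone genes were not called as a list, with 2 of 14 higher and 4 lower (the same counts adjusted over the list alone; adjusted p = 0.344). In that list Sst had −0.83 ± 0.31 (adjusted p = 0.0012), Gcg −0.45 ± 0.52 (adjusted p = 0.053, negative in 5 of 6 arrays) and Ppy −0.87 ± 1.21 (adjusted p = 0.065, negative in 4 of 6 arrays). Of 10 islet autoantigens 8 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0475, and adjusted p = 0.631 with an estimated correlation). This call was lost without 4-week replicate 2 (adjusted p = 0.0528), 3 (0.0908), 4 (0.0615) or 5 (0.0622), with scaling between arrays (0.0506), the strict filter (0.0707), array weights (0.07) and slide as a random block (0.0501), and without the arrays that stand apart (0.0534). Of 19 genes kept low in mature beta cells 13 were higher and 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.000108, and adjusted p = 0.436 with an estimated correlation). Lactate dehydrogenase A, Ldha, had 1.40 ± 0.17.

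Cell cycle genes were lower at 4 weeks, 20 of 29 with 1 higher (22 and 1 adjusted over the list alone; camera adjusted p = 0.00013, and adjusted p = 0.591 with an estimated correlation), and Cdc20 had −1.07 ± 0.16. Of 26 genes of oxidative phosphorylation 13 were higher and 4 lower, also adjusted over the list alone, with a median of 0.10 whose direction flipped under median centring (−0.048, adjusted p = 0.848). The camera adjusted p was 0.0369 (adjusted p = 0.707 with an estimated correlation), and the call was lost without 4-week replicate 3 (0.0594) or 5 (0.0664), without the arrays that stand apart (0.0666), and with the processed signals (0.0689), the deposited values (0.069), offset 16 (0.069) and array weights (0.0523). Of 31 genes of the type I interferon response 5 were higher and 0 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.0253, and adjusted p = 0.851 with an estimated correlation). That share of higher genes lay below the share over all genes, 4735 of 18099. Bst2, an interferon-induced membrane protein that tethers virions, had 0.99 ± 0.42 (6 of 6 arrays), whereas Isg15, an interferon-induced ubiquitin-like protein, had 0.66 ± 1.35 (adjusted p = 0.12, positive in 4 of 6 arrays). The interferon call was lost without 4-week replicate 2 (adjusted p = 0.0704), replicate 4 (0.554) or replicate 6 (0.0655). The interferon-gamma list had 9 of 31 genes higher and 0 lower (4 and 0 adjusted over the list alone) and was not called (adjusted p = 0.0508), though 11 of 22 alternatives called it higher (adjusted p from 0.00433 to 0.0422). Its share of higher genes was near that over all genes. The MHC list had 1 of 20 genes higher and 9 lower (0 and 9 adjusted over the list alone) and was not called (adjusted p = 0.063), though 9 of 22 alternatives called it lower (adjusted p from 0.00776 to 0.0457). The Reg family had 2 of 6 genes higher and was not called (2 adjusted over the list alone; adjusted p = 0.257) unless the arrays that stand apart were left out (1.20, adjusted p = 0.037), and Reg2 and Reg3b spread more between the mice than other named genes, with SDs of 3.03 and 2.84. Of 25 T cell genes 3 were higher and 1 lower (3 and 0 adjusted over the list alone; adjusted p = 0.613, and 0.0151 with a median of 0.113 under median centring), and Cd3e had 0.60 ± 0.24 (adjusted p = 6.5e-06, 6 of 6 arrays). Of 22 B cell genes limma called 0 in either direction, also adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.932). On the B cell list 4-week replicate 5 stood apart, at 0.82 against −0.22 to −0.15. On the macrophage list, with 1 of 25 genes higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.764), it stood at 0.59 against −0.48 to −0.08.

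With limma, 9790 genes were called at 4 weeks, 4735 higher and 5055 lower, and 503 passed the 2-fold threshold, 345 higher and 158 lower. Under median centring 22.3% of the called and 17% of the 2-fold genes were higher, against 48.4% and 68.6%. The processed signals gave 2131 2-fold calls, 59.1% of them higher.

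**Figure D2:**
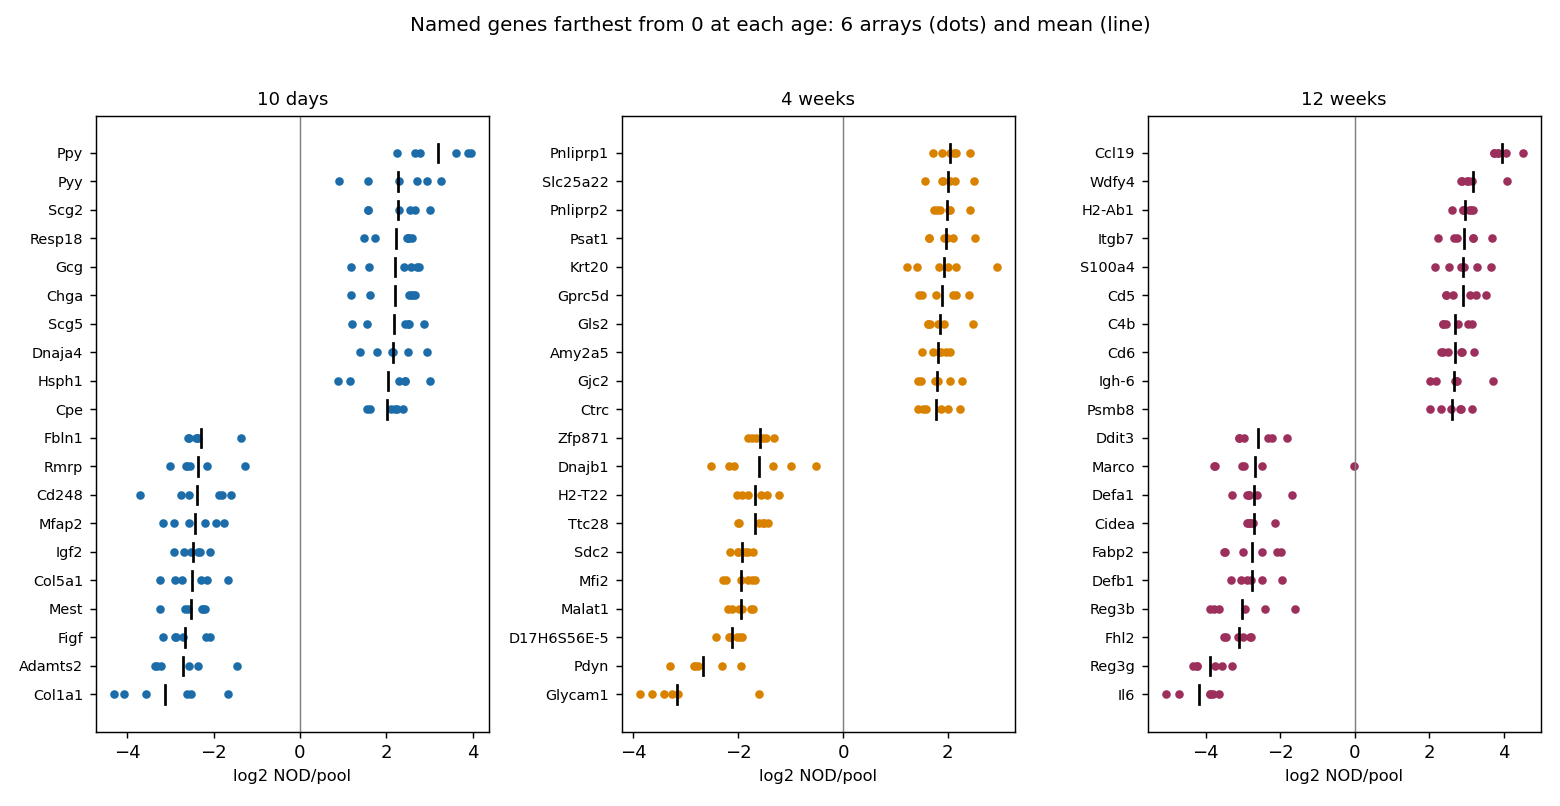
Log2 ratio (NOD over NOD.B10 pool) of the 10 highest and 10 lowest named genes at each age, with 1 dot per array (6 per age) and a line at the mean. Col1a1 lies at −3.13 at 10 days, Pnliprp1 at 2.05 at 4 weeks, and Ccl19 at 3.95 and Il6 at −4.17 at 12 weeks.

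At 12 weeks genes of lymphocytes, antigen presentation and cell division were higher in the NOD islets, and Il6, Reg family genes and duct genes were lower. Ccl19, a chemokine that draws T cells and dendritic cells into lymphoid tissue, was highest at 3.95 ± 0.30 (mean ± SD, n = 6; adjusted p = 1.5e-05), followed by Wdfy4, which is needed for cross-presentation, at 3.17 ± 0.47 (adjusted p = 5.1e-06), and the MHC class II gene H2-Ab1 at 2.96 ± 0.20 (adjusted p = 2e-06). Ifng, which encodes interferon-gamma, was higher by 2.43 ± 0.61 (adjusted p = 1.7e-07). The lowest were Il6, a cytokine of inflammation, at −4.17 ± 0.58 (adjusted p = 4.4e-07) and Reg3g, an antimicrobial lectin, at −3.90 ± 0.43 (adjusted p = 2.2e-06). Each had the same sign in 6 of 6 arrays.

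Of 25 T cell genes 23 were higher at 12 weeks and 0 lower (24 and 0 adjusted over the list alone; camera adjusted p = 1.12e-09, and adjusted p = 0.509 with an estimated correlation). Higher T cell genes included the surface receptors Cd5 (2.90 ± 0.45) and Cd6 (2.69 ± 0.35), the kinase Lck (2.45 ± 0.60) and Cd8a (1.53 ± 0.55, pool signal well above background on 3 of 6 arrays). Cd3e was not called (0.18 ± 0.13, adjusted p = 0.074, positive in 5 of 6 arrays), and Cd4 was at least 1.11-fold higher, its pool signal being not well above background. Of 22 B cell and plasma cell genes 20 were higher and 0 lower (21 and 0 adjusted over the list alone; camera adjusted p = 1.23e-07, and adjusted p = 0.509 with an estimated correlation). Higher B cell genes included the immunoglobulin mu chain, Igh-6, at 2.67 ± 0.59 and the inhibitory receptor Cd72 at 2.03 ± 0.34. Of 17 cytotoxic and NK cell genes 14 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.501 with an estimated correlation). The granule protein Nkg7 had 2.57 ± 0.52. The cytotoxic list was not called under median centring (0.324, adjusted p = 0.122). Of 25 macrophage and monocyte genes 20 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 7.87e-07, and adjusted p = 0.509 with an estimated correlation). Its members included the complement genes C1qa (1.32 ± 0.25), C1qb (1.31 ± 0.28) and C1qc (1.73 ± 0.28). In contrast, the scavenger receptor Marco had −2.68 ± 1.39, a call that median centring ended (−1.72, adjusted p = 0.07). Of 12 dendritic cell genes 8 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00208, and adjusted p = 0.509 with an estimated correlation). The integrin Itgax had 1.79 ± 0.35. The T cell regulation and exhaustion list had 11 of 15 genes higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.000941, and adjusted p = 0.509 with an estimated correlation). The costimulatory receptor Tnfrsf4 had 2.05 ± 0.44. The call of this list was lost under median centring (0.081, adjusted p = 0.36).

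The MHC list had 16 of 20 genes higher at 12 weeks and 2 lower (17 and 2 adjusted over the list alone; camera adjusted p = 2.8e-06, and adjusted p = 0.509 with an estimated correlation). H2-Aa had 2.47 ± 0.24 and H2-Eb1 2.37 ± 0.15, while H2-K1 was not called (0.52 ± 0.51, adjusted p = 0.074, positive in 5 of 6 arrays). Probes of H2-Aa and of H2-K1 included called ones of opposite sign at 12 weeks, and the strains differ in their MHC haplotype. Of 31 genes of the interferon-gamma response and antigen processing 21 were higher and 1 lower (25 and 2 adjusted over the list alone; camera adjusted p = 5.24e-06, and adjusted p = 0.518 with an estimated correlation). The immunoproteasome subunit Psmb8 had 2.62 ± 0.40 and the chemokine Cxcl9 2.54 ± 0.41. The type I interferon list was split, with 6 of 31 higher and 7 lower (7 and 7 adjusted over the list alone; adjusted p = 0.71). Of 29 cell cycle genes 27 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 4.83e-12, and adjusted p = 0.501 with an estimated correlation). Mcm3, a subunit of the replicative helicase, had 1.94 ± 0.41 and Birc5, which acts in mitosis, 1.91 ± 0.44. Mesenchymal genes were higher too, 10 of 20 with 0 lower (12 and 0 adjusted over the list alone; camera adjusted p = 0.00923, and adjusted p = 0.716 with an estimated correlation). The collagen gene Col1a2 had 1.44 ± 0.38. On this mesenchymal list 12-week replicate 5 stood apart (values below). The means of the T cell, B cell, macrophage, MHC and cell cycle lists lay above 0 in 6 of 6 arrays at 12 weeks.

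Beta cell identity genes were lower at 12 weeks, 14 of 25 with 1 higher (15 and 1 adjusted over the list alone; camera adjusted p = 3.3e-05, and adjusted p = 0.571 with an estimated correlation). Median centring ended this call (−0.173, adjusted p = 0.0926). Ins2 had −1.25 ± 0.39 (adjusted p = 0.00034) and Slc2a2 −1.14 ± 0.89 (adjusted p = 0.0016), both in 6 of 6 arrays. Under median centring both lay near 0 (−0.02 and −0.06) and still below the median of all genes. So did Ins1, which had −1.05 ± 0.33 and turned to 0.16 under it. The granule list had 5 of 17 genes lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.0458, and adjusted p = 0.817 with an estimated correlation), a direction that flipped under median centring (0.127, adjusted p = 0.745). It lost its call without 12-week replicate 1 (0.0605), 4 (0.0627), 5 (0.0548) or 6 (0.104). The same call was lost with the processed signals and the deposited values (0.052 for both), offset 16 (0.0522), scaling between arrays (0.0722), no filter (0.0547), the strict filter (0.0786) and slide as a random block (0.0543). Of 10 autoantigens 5 were lower and 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.037, and adjusted p = 0.597 with an estimated correlation). This call was lost under median centring (−0.235, adjusted p = 0.266), with the processed signals and the deposited values (−0.76, adjusted p = 0.108 for both), offset 16 (0.054), scaling between arrays (0.053) and the strict filter (0.0604), and without 12-week replicate 4 (0.0667) or 5 (0.0646). The endoplasmic reticulum stress list had 15 of 25 genes lower and 2 higher, also adjusted over the list alone (camera adjusted p = 1.5e-06, and adjusted p = 0.471 with an estimated correlation), with a median whose direction relative to all genes flipped under median centring (0.091, adjusted p = 0.456). Ddit3, a transcription factor of the stress response, had −2.59 ± 0.55 and the chaperone Hsp90b1 −1.33 ± 0.19, the latter not called under median centring (−0.14, adjusted p = 0.503). The oxidative stress defence list had 11 of 22 lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.00217, and adjusted p = 0.436 with an estimated correlation). The metallothioneins Mt1 and Mt2 had −2.27 ± 0.69 and −2.17 ± 0.67, and the direction of the list's median flipped under median centring as well (0.021, adjusted p = 0.377).

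Of 6 Reg genes 4 were lower at 12 weeks and 0 higher, also adjusted over the list alone (camera adjusted p = 0.00964, and adjusted p = 0.518 with an estimated correlation). Reg3b had −3.04 ± 0.90 (adjusted p = 0.0012) and Reg2 −2.15 ± 0.90 (adjusted p = 0.022), both in 6 of 6 arrays. Without 12-week replicate 2, 4 or 6 Reg2 was no longer called (−1.85, −2.12 and −2.08 with adjusted p = 0.0702, 0.0501 and 0.0511). Median centring ended the call of Reg2 (−0.94, adjusted p = 0.24) and left Reg3b at −1.89 (adjusted p = 0.0135). Of 15 duct genes 10 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.494 with an estimated correlation). The keratins Krt8 and Krt19 had −2.12 ± 0.50 and −1.98 ± 0.21. Other genes among the 10 lowest were Fabp2, the intestinal fatty acid binding protein, at −2.75 ± 0.68, the defensin Defb1 at −2.76 ± 0.48, and Defa1, at least 6.37-fold lower because its NOD signal was not well above background. Lists of intestinal epithelium genes and of genes induced by cytokines or isolation were written after these lowest genes were seen, and are given below. Acinar genes were not called, with 2 of 28 higher and 2 lower (1 and 1 adjusted over the list alone; adjusted p = 0.478). The other islet hormones were not called either, with 4 of 14 higher and 1 lower (the same counts adjusted over the list alone; adjusted p = 0.684).

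With limma, 7457 genes were called at 12 weeks, 4278 higher and 3179 lower, and 637 passed the 2-fold threshold, 378 higher and 259 lower. Under median centring 12074 genes were called, 93.4% of them higher against 57.4%. Under it 4296 passed the 2-fold threshold, 99.2% of them higher against 59.3%. The processed signals gave 3254 2-fold calls, 64.6% of them higher.

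The change between ages was tested as the difference of the ratios, so that it can come from either strain. From 10 days to 4 weeks the beta cell and granule lists fell relative to the pool, and the acinar and mesenchymal lists rose. Ppy fell by 4.07 on the log2 scale (SE 0.54, adjusted p = 8.5e-06) and Chga, chromogranin A, fell by 2.93 (SE 0.25, adjusted p = 1e-07). Celsr1, a cadherin of planar cell polarity, rose by 3.26 (SE 0.29, adjusted p = 1.7e-07) and Col1a1 by 3.21 (SE 0.39, adjusted p = 3.1e-06), each over 6 arrays per age. Slide 2 held 2 arrays of each of these ages, and within it Ppy changed by −4.72 (adjusted p = 0.00611), Chga by −3.32 (0.00182), Celsr1 by 3.36 (0.00223) and Col1a1 by 3.15 (0.0238).

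Of 25 beta cell genes 24 fell from 10 days to 4 weeks (adjusted p = 4.83e-12, and adjusted p = 0.501 with an estimated correlation). The list mean changed by −2.19 within slide 2 and by −1.82 over all arrays. The granule list fell in 16 of 17 genes (adjusted p = 6.76e-10, and adjusted p = 0.501 with an estimated correlation). Its mean changed by −2.22 within slide 2 and −1.91 over all arrays. On the arrays the granule level of the pool channel changed by 2.14 between these ages and that of the NOD channel by 0.23. Acinar genes rose in 25 of 28 (26 adjusted over the list alone; adjusted p = 5.69e-07, and adjusted p = 0.585 with an estimated correlation). The acinar mean changed by 1.73 within slide 2 and 1.53 over all arrays. Mesenchymal genes rose in 17 of 20 (adjusted p = 2.37e-07, and 0.509 with an estimated correlation). The mesenchymal mean changed by 1.74 and 1.53. The mesenchymal level changed by −2.28 in the pool channel and −0.76 in the NOD channel, whereas the acinar level changed by −0.49 in the pool and 1.04 in NOD. The endothelial list rose in 9 of 18 genes (adjusted p = 0.037, and adjusted p = 0.828 with an estimated correlation). It lost its call with slide as a block (adjusted p = 0.349), under median centring (0.029, adjusted p = 0.61), with array weights (0.127) and without 10-day replicate 2 (0.108) or 4 (0.126) or 4-week replicate 2 (0.0528) or 5 (0.0907). The Reg family rose in 4 of 6 genes (adjusted p = 0.0458, and 0.632 with an estimated correlation). Its mean changed by 3.46 within slide 2 and 2.07 over all arrays. That call was lost without 10-day replicate 1 (0.0566), 4 (0.0514) or 5 (0.0541) and without 4-week replicate 1 (0.0714), 2 (0.0704), 4 (0.0837) or 6 (0.0641). It was also lost with scaling between arrays (0.152), no filter (0.0639), the strict filter (0.0538), a variance trend (0.0586) and slide as a random block (0.0689). For the beta cell, granule, mesenchymal, endothelial and Reg lists the counts were the same adjusted over the list alone.

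With limma, 9684 genes changed from 10 days to 4 weeks, 4624 up and 5060 down, and 1648 by at least 2-fold. With slide as a block, over the same arrays and pools, 4417 changed, of which 4370 were also among the 9684 and in the same direction. Under median centring 14.5% of the called and 1.9% of the 2-fold changes were upward, against 47.7% and 57.6%.

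**Figure D3:**
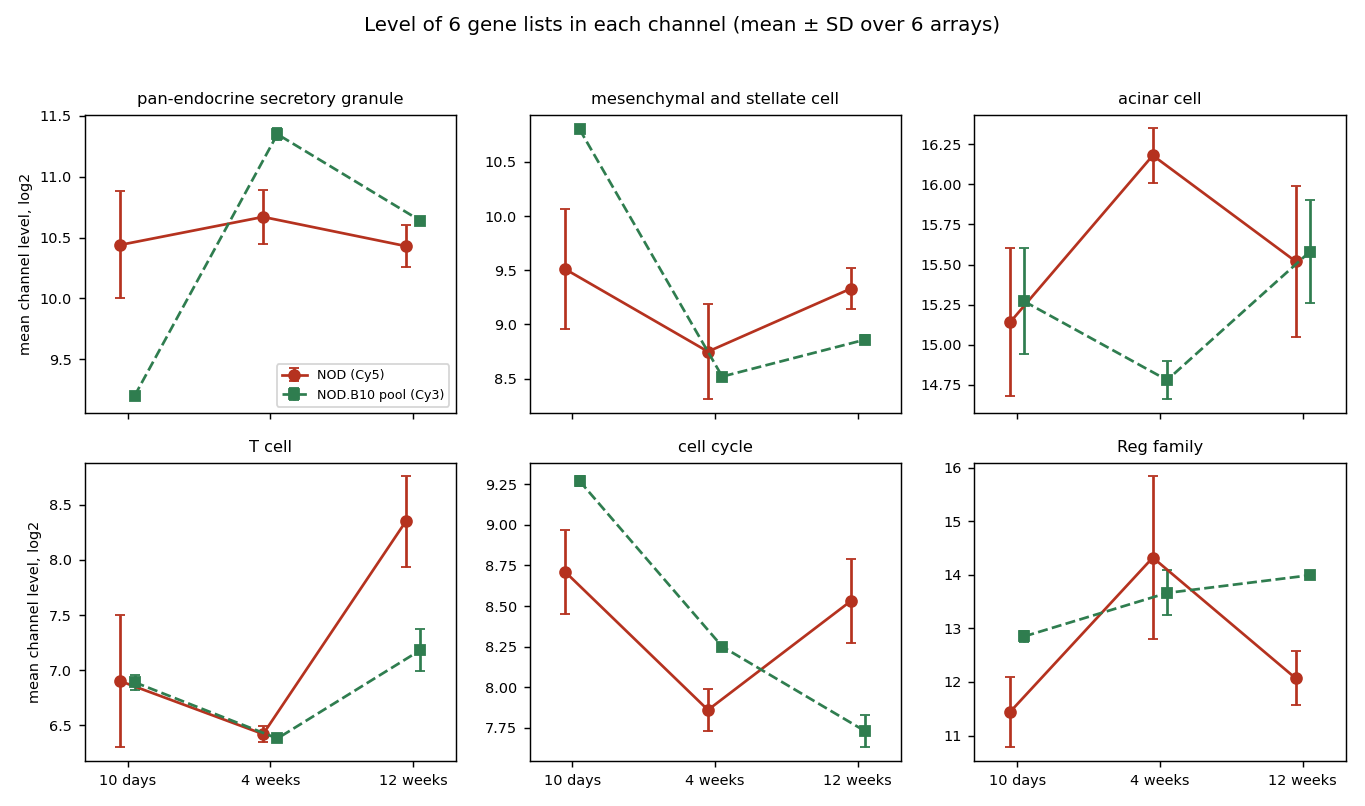
Mean log2 level of 6 gene lists in the NOD channel (Cy5, solid lines with circles) and the pool channel (Cy3, dashed lines with squares) at each age, with the mean ± SD of 6 arrays. The pool bars come from 1 pool hybridised 6 times, so they hold the spread of the assay and the normalization and not that between mice. The granule level of the pool changed by 2.14 from 10 days to 4 weeks and that of NOD by 0.23, and the T cell level, partly at the background, changed from 4 weeks to 12 weeks by 1.93 in NOD and 0.80 in the pool.

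From 4 weeks to 12 weeks the MHC, T cell, B cell and cell cycle lists rose relative to the pool, and the acinar, Reg, duct and endoplasmic reticulum stress lists fell. Ccl19 rose by 4.64 (SE 0.76, adjusted p = 0.00017) and Cd74, the invariant chain of MHC class II, by 2.99 (SE 0.47, adjusted p = 0.00012). Glycam1 rose by 4.69 (SE 0.69, adjusted p = 7.3e-05), from its low value at 4 weeks. Reg3g fell by 4.32 (SE 0.63, adjusted p = 6.4e-05) and Il6 fell by 3.90 (SE 0.58, adjusted p = 7.9e-05), each over 6 arrays per age.

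The MHC list rose in 18 of 20 genes with 0 falling from 4 to 12 weeks (adjusted p = 4.13e-08, and adjusted p = 0.509 with an estimated correlation), from a median of −0.33 at 4 weeks to 0.83 at 12 weeks. The cell cycle list rose in 27 of 29 (adjusted p = 1.04e-13, and 0.494 with an estimated correlation). Both lists had the same counts adjusted over the list alone. Of 25 T cell genes 20 rose and 2 fell, also adjusted over the list alone (adjusted p = 1.44e-05, and adjusted p = 0.518 with an estimated correlation). Of 22 B cell genes 19 rose and 0 fell, also adjusted over the list alone (adjusted p = 2e-05, and adjusted p = 0.521 with an estimated correlation). Median centring ended both calls, with shifts relative to all genes of 0.728 (adjusted p = 0.259) for T cells and 0.858 (adjusted p = 0.0701) for B cells. The T cell level changed by 1.93 in the NOD channel and 0.80 in the pool channel, and the B cell level by 2.29 and 1.26. At 4 weeks 9 of 25 T cell genes and 8 of 22 B cell genes were well above background on at least 3 of 6 arrays in the NOD channel, and 15 and 14 in the pool, so that these changes are partly measured from the floor. The MHC level changed by 2.6 in NOD and 1.10 in the pool, the cell cycle level by 0.67 and −0.52, the acinar level by −0.66 and 0.80, and the Reg level by −2.25 and 0.33. Acinar genes fell in 25 of 28 (27 adjusted over the list alone; adjusted p = 2.17e-09, and adjusted p = 0.509 with an estimated correlation). Endoplasmic reticulum stress genes fell in 19 of 25 with 1 rising (20 and 1 adjusted over the list alone; adjusted p = 2.17e-09, and adjusted p = 0.436 with an estimated correlation). Duct genes fell in 11 of 15 with 1 rising, also adjusted over the list alone (adjusted p = 0.000213, and adjusted p = 0.436 with an estimated correlation). The Reg family fell in 4 of 6, also adjusted over the list alone (adjusted p = 0.00348, and adjusted p = 0.509 with an estimated correlation). The granule list rose in 9 of 17 with 0 falling (10 and 0 adjusted over the list alone; adjusted p = 0.00964, and adjusted p = 0.707 with an estimated correlation). The beta cell list was not called, with 7 of 25 up and 1 down (the same counts adjusted over the list alone; adjusted p = 0.182), other than with no filter (0.0497). With limma, 8313 genes changed, 4734 up and 3579 down, and 1123 by at least 2-fold. Under median centring 12512 changed, 92.2% of them upward against 56.9%. The arrays of 12 weeks shared no slide with another age, so that no value within a slide can be given.

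From 10 days to 12 weeks the T cell, B cell, mesenchymal and cell cycle lists rose relative to the pool and the beta cell list fell. Igh-6 rose by 4.08 (adjusted p = 0.00036), Col1a1 by 3.99 (SE 0.39, adjusted p = 5e-07) and Cd52, a lymphocyte surface protein, by 3.67 (adjusted p = 0.00032). Defb1, whose pool signal was well above background on 5 of 6 arrays at 10 days, fell by 4.02 (SE 0.29, adjusted p = 3.2e-08) and Ins2 fell by 3.08 (SE 0.33, adjusted p = 1.2e-06). Of 25 T cell genes 21 rose and 0 fell, also adjusted over the list alone (adjusted p = 2.8e-06, and adjusted p = 0.509 with an estimated correlation). Of 22 B cell genes 21 rose and 0 fell (22 and 0 adjusted over the list alone; adjusted p = 3.16e-07, and adjusted p = 0.509 with an estimated correlation). All 29 cell cycle genes rose (adjusted p = 1.17e-15, and 0.469 with an estimated correlation). Of 20 mesenchymal genes 17 rose (adjusted p = 9.92e-09, and 0.509 with an estimated correlation). Of 25 beta cell genes 23 fell (adjusted p = 6.59e-12, and 0.501 with an estimated correlation). These last 3 lists had the same counts adjusted over the list alone. In the channels the cell cycle level changed by −1.54 in the pool and −0.18 in NOD, the mesenchymal level by −1.94 and −0.17, and the beta cell level by 1.64 and 0.09. The T cell level changed by 0.29 in the pool and 1.46 in NOD, and the B cell level by 0.54 and 1.91. With limma, 8461 genes changed, 4506 up and 3955 down, and 1587 by at least 2-fold. Under median centring 4541 changed, 62.9% of them upward against 53.3%, and 74.2% of the 2-fold changes were upward against 57.5%.

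Across the mice of 1 age, the means of the T cell and B cell lists went together at 12 weeks, with Pearson's r = 0.97 over 6 mice (exact permutation p = 0.00278; adjusted p = 0.0334 over 12 relations). Spearman's rho was 0.94 (exact permutation p = 0.0167, adjusted p = 0.0668), and r was 0.96 without the 2 mice farthest from the median. With the median of the members in place of the mean r was 0.95 (adjusted p = 0.05), and with the processed signals it was 0.92 (adjusted p = 0.1). At 10 days r between the T and B cell lists was 0.93 (exact permutation p = 0.00972, adjusted p = 0.0583), and at 4 weeks 0.80 (exact permutation p = 0.147, adjusted p = 0.352), where it rested on the 2 farthest mice (−0.33 without them). The T cell and beta cell lists had r = −0.72 at 12 weeks (exact permutation p = 0.0917, adjusted p = 0.275; −0.15 without the 2 farthest mice). The acinar and beta cell lists had r = −0.79 at 10 days (exact permutation p = 0.0347, adjusted p = 0.139) and rho = −1 (exact permutation p = 0.00278, adjusted p = 0.0334), and r was −0.95 without the 2 farthest mice. The mice of an age lay on 2 slides. Over deviations from the slide means, an alternative added after seeing the data, r between the T and B cell lists was 0.98 at 12 weeks (exact permutation within slides p = 0.0208, the smallest these 48 permutations allow; adjusted p = 0.125). It was 0.95 at 10 days and 0.83 at 4 weeks, and that between the acinar and beta cell lists at 10 days was −0.93 (exact permutation p = 0.0208, adjusted p = 0.125).

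Across the ages, 840 genes were called higher at all 3 and 562 lower, against 320.19 and 229.88 if the ages were independent. Without a dye swap a gene-specific dye bias would repeat at each age and could by itself raise both counts above this expectation. The excess therefore cannot tell it from a lasting difference between the strains. At the 2-fold threshold 5 genes were lower at all 3 ages, named here after their values were seen except for those that were already among the lowest of an age. Sdc2, the proteoglycan syndecan 2 (chromosome 15, 32962294 to 32962353, mm9, the span of its probe), had −1.71, −1.93 and −1.64 at 10 days, 4 weeks and 12 weeks. Fosb, an immediate early transcription factor (chromosome 7, 19888477 to 19888536), had −1.71, −1.33 and −1.04. The other 3 lay on chromosome 17, Zfand3 (30346773 to 30346832) with −1.29, −1.35 and −1.29, the zinc finger gene Zfp871 (32910629 to 32910688) with −1.29, −1.58 and −1.23, and D17H6S56E-5 (35134128 to 35134187) with −2.01, −2.11 and −1.14. Zfp871 had called probes of both signs at 4 weeks. The 1 gene higher by 2-fold at all ages was the transcript NAP058332-1 (chromosome 13, 15211246 to 15211483), with 1.28, 1.19 and 1.19.

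Genes lower at all 3 ages were more frequent on chromosome 17, which carries the mouse MHC, with 46 of 875 genes (5.26%) against 514 of 17020 on other chromosomes (3.02%; odds ratio 1.78, 95% confidence interval 1.28 to 2.43, Fisher's exact p = 0.000633, two-sided). Under median centring only 4 genes of chromosome 17 were lower at all 3 ages, all of them between 28 and 40 Mb, and the excess over other chromosomes was 0.35 percentage points (Fisher's exact p = 0.0205) in place of 2.24. Genes higher at all 3 ages were not, with 39 of 875 (4.46%) against 795 of 17020 (4.67%; Fisher's exact p = 0.869). Within chromosome 17 the part from 28 to 40 Mb, around the MHC, had 13 of 268 genes lower (4.85%) and the rest 33 of 607 (5.44%; Fisher's exact p = 0.87), a difference that changed direction at the 2-fold threshold, with 3 of 268 against 0 of 607 (p = 0.0285), and under median centring. Of the 46 genes 20 had other probes that entered, and 4 of those 31 probes (12.9%) were themselves lower at all 3 ages, against 33 of 318 (10.4%) for such genes on other chromosomes.

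**Figure D4:**
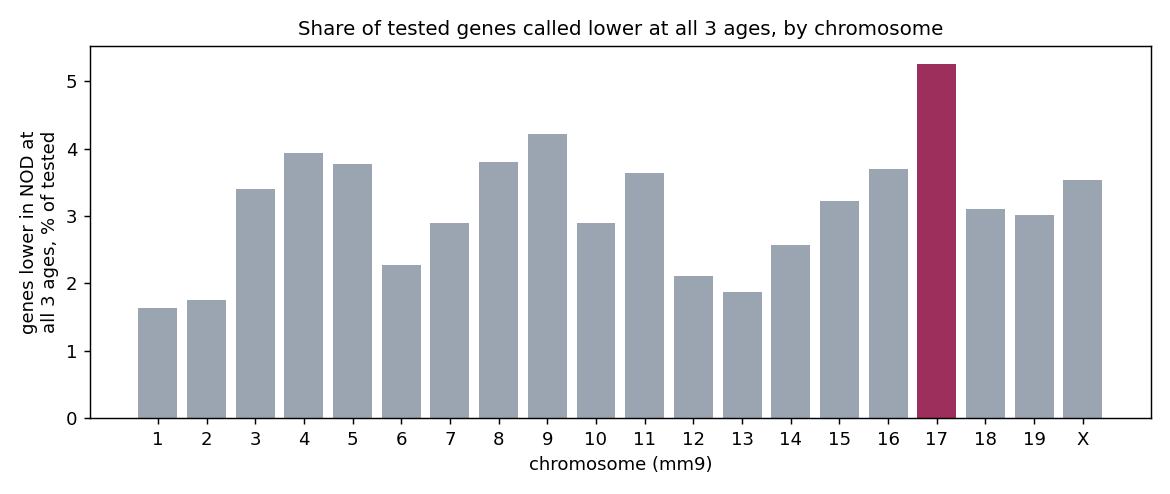
Share of the tested genes of each autosome and chromosome X (mm9) that were called lower in NOD at all 3 ages, in percent. Chromosome Y, with 3 tested genes, is not shown. Among those shown chromosome 17 had 5.26%, the next highest chromosome 9 had 4.21% and the lowest, chromosome 1, had 1.63%.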

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

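The tests in this part on the share of endocrine tissue, on the slide, on the pools and on dye bias were chosen after the results were seen, while those on other splits of the arrays, on intestinal tissue, on a cytokine response and on strain variants under the probes were written before theirs.

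The difference between NOD and the pool changed between ages for 9684 genes from 10 days to 4 weeks, 8461 from 10 days to 12 weeks and 8313 from 4 to 12 weeks. The arrays were also split in other ways, with only the 2 ages compared in the fit, where the real split gave 8908 genes from 10 days to 4 weeks, 8255 from 10 days to 12 weeks and 8799 from 4 to 12 weeks. In each comparison 1 of 100 splits, the real one, gave as many. The highest other splits, which swapped 1 array of each age, gave 4943, 2438 and 2790. For a single age the signs of its arrays, fitted alone, were turned in all 32 ways, and 1 of 32, the real one, gave as many genes at each age. The real counts were 8041 at 10 days against 4 in the highest other pattern, 9053 against 3 at 4 weeks and 8513 against 0 at 12 weeks. Chance in how the mice fall into ages, or in their signs, can therefore be excluded for these counts. Neither kind of split tests a deviation of the single pool that all arrays of an age share, so that chance at the level of the pools stays open for the single ages and for the changes between them, and turned signs do not test a dye bias.

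By the test of the difference between ages, 27 lists changed between at least 1 pair of ages, each given here as its median log2 change where the test was strongest. From 10 days to 4 weeks these were beta cell identity (−1.90), other islet hormones (−1.26), the pan-endocrine granule list (−1.97), genes low in mature beta cells (0.97) and adipocyte genes (1.53). From 4 to 12 weeks they were acinar (−1.54), Reg (−2.14), duct (−0.74), red blood cell (−1.86), type I interferon (−0.40), endoplasmic reticulum stress (−0.79), MHC (1.51) and T cell regulation (0.37). From 10 days to 12 weeks they were endothelial (0.72), mesenchymal (1.60), Schwann cell (1.00), T cell (0.76), cytotoxic (0.64), B cell (1.14), macrophage (1.04), dendritic cell (0.89), interferon-gamma (0.96), lymphoid organisation (0.56), oxidative stress (−0.15), cell cycle (1.31), autoantigen (−1.65) and circadian genes (−0.25). Several of these calls were lost under alternatives. The type I interferon change was lost without 4-week replicate 4 (−0.17 relative to all genes, adjusted p = 0.441), 2 (0.0855) or 6 (0.0739) and without 12-week replicate 1 (0.0679), 3 (0.0743) or 6 (0.104). It was also lost with the processed signals and the deposited values (0.0502 for both), no filter (0.103), the strict filter (0.0574), every probe on its own (0.0654) and each age alone (0.0531). The oxidative stress change was lost with the processed signals (0.0597), the deposited values (0.0595), median centring (0.0514) and without 10-day replicate 4 (0.0642), and the circadian change with the strict filter (0.0523) and every probe on its own (−0.069, adjusted p = 0.0524). The strict filter also ended the adipocyte (0.299), cytotoxic (0.0574) and lymphoid organisation (0.0559) calls, no filter that of red blood cells (0.0562), and median centring that of T cell regulation, which turned to −0.155 (0.744). With an estimated correlation none of these list changes held, with adjusted p of at least 0.436.

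The first pattern is that the beta cell and granule lists stood opposite to stromal lists at 10 days and to the acinar list at 4 weeks, with a fall of the granule list in between. A different share of endocrine tissue alone would move all other cell types alike. The duct list exceeded the mesenchymal list by 1.42 ± 0.96 at 10 days and the acinar list exceeded the endothelial list by 1.65 ± 0.51 at 4 weeks (SD, n = 6; exact sign permutation p = 0.031 for both, the smallest possible). These pairs were picked from lists already seen to differ, and the 6 arrays of an age share 1 pool. The p-values therefore cannot decide it, and the values show only that these lists did not shift alike on these arrays. The slide alone is argued against by the change of −2.22 in the granule list within slide 2, which holds both ages. The granule level changed by 2.14 in the pool channel and 0.23 in the NOD channel, sizes that differ by 1.91, beyond the SD of 0.44, so that the pools may carry the fall, a test written after the levels were seen that could not establish it. Whether pool or mouse islets held other shares of tissue, or the strains differ in expression at these ages, stays open and was not tested.

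The second pattern is that Il6, Reg genes, the intestinal fatty acid binding protein Fabp2 and the defensin Defb1 were lower at 12 weeks. For intestinal tissue in the 12-week pool, 19 genes of an intestinal list (1 also on the acinar list, and 10 above background in the 10-day pool) had a median of −0.49 with 11 lower and 0 higher, just short of the bound of −0.5 set beforehand, though the most abundant in the pool, Zg16 (the one on the acinar list) and Dmbt1, differed by −0.05 and −0.14, while Lgals4 had −1.41. For a cytokine or isolation response in that pool, 20 induced genes (5 also on other lists, and 16 above background in the 10-day pool) had a median of −0.22 with 9 lower and 1 higher, where Cebpd had −2.23 and Nfkbia, the most abundant, −0.40. At 10 days, with another pool, these induced genes had a median of −0.54 with 10 lower and 2 higher. At 4 weeks their median was 0.09 with 1 lower and 3 higher. Lower values of this list were thus not particular to the 12-week pool. The cytokine median at 12 weeks met the bound set against its explanation but the 9 lower genes did not, and the intestinal values met none against theirs, so both may contribute and cannot be told apart from these lists. A difference between the strains at this age also stays open and was not tested.

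The third pattern is that genes lower at all 3 ages were frequent on chromosome 17. The odds ratio of 1.78 (Fisher's exact p = 0.000633) is the pattern itself and decides nothing about a gene-specific dye bias, which stays open without a dye swap. Under median centring only 4 such genes lay on this chromosome, with an excess of 0.35 percentage points (Fisher's exact p = 0.0205) in place of 2.24. Strain variants under the probes could lower the NOD signal where the strains differ in sequence, and 12.9% of the 31 other probes of those genes were lower at all ages, between the bounds of 10% and 50% set beforehand, which leaves it open. Expression that differs between the strains on this chromosome stays open too, as untested.

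Single arrays stood apart from the other 5 of their age in 7 of 93 sets of list values and 15 of 249 sets of values of named genes, where chance gives about 1 in 20. At 10 days replicate 1 stood apart on the neutrophil and mast cell list (0.50, others −0.35 to −0.12), on chemokines (0.05, others −0.69 to −0.42) and on Fbln1 (−1.37, others −2.58 to −2.37), and replicate 2 on the type I interferon list (0.89, others −0.09 to 0.19). At 4 weeks replicate 5 stood apart on the B cell list (0.82, others −0.22 to −0.15), the macrophage list (0.59, others −0.48 to −0.08) and the neutrophil and mast cell list (0.98, others 0.01 to 0.29), and on Ldha (1.07), Cxcl13 (2.28, well above background on 1 of 6 arrays in either channel) and Glycam1 (−1.60). Replicate 3 of the same age stood apart on Gls2 (2.47), Cd4 (0.62, pool well above background on 3 of 6 arrays), Ica1 (0.61) and Ins1 (−2.31). At 12 weeks replicate 5 stood apart on the mesenchymal list (0.80, others 0.34 to 0.49) and Mgp (1.76), replicate 4 on Wdfy4 (4.10) and Marco (−0.02, others −3.77 to −2.49), and replicate 2 on Cd3e (−0.09), Cidec (−0.25, NOD well above background on 2 of 6 arrays), Cftr (−0.61) and Cidea (−2.14).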

How the results depend on the processing

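Leaving out together the arrays that stand apart on a list of another cell type and centring list means on the slide were chosen after seeing the data, and all other alternatives before. Of the 186 list results the call and direction stayed in 164 of 180 (strict filter) to 184 (variance trend) under every alternative other than median centring (137) and an estimated correlation (95), leave-one-out aside, and with slide as a fixed block in 28 of 31 list results and 20 of 20 gene results of the change from 10 days to 4 weeks. Of the 309 named gene results they stayed in 298 (slide as a random block) to 309 (every probe on its own), other than median centring (249) and the strict filter (276 of 277 measured). Without the arrays that stand apart 174 lists and 301 genes stayed the same. A change of sign where neither setting passed its threshold was counted as no change. The cause of the changes that follow was not tested, other than where the construction is named. The processed signals gave 2926, 2131 and 3254 2-fold calls at 10 days, 4 weeks and 12 weeks and 4643, 4826 and 4500 for the changes from 10 days to 4 weeks, 10 days to 12 weeks and 4 to 12 weeks, against 717, 503, 637, 1648, 1587 and 1123. The deposited values gave 2925, 2130, 3253, 4644, 4825 and 4498. The 1.5-fold threshold gave 2650, 2152, 1888, 3985, 3679 and 3028, more by its construction. Offset 16 gave 1104 2-fold calls at 10 days and scaling between arrays 1035 at 12 weeks. Median centring gave 2764, 802, 4296, 5928 and 7162 2-fold calls (all but the change from 10 days to 12 weeks) and 12074, 4541 and 12512 called genes at 12 weeks, from 10 days to 12 weeks and from 4 to 12 weeks. By its construction it leaves in any trend of the ratio with brightness. Slide as a fixed block called 4417 genes from 10 days to 4 weeks. With 1 array left out in turn the called genes ranged from 8781 to 9533, 8676 to 9580, 6206 to 7229, 8958 to 9833, 7626 to 8369 and 7401 to 8507 in the same order, and the 2-fold calls from 648 to 806, 413 to 601, 559 to 707, 1551 to 1756, 1476 to 1691 and 1014 to 1311. Median centring turned the direction of the list test for T cell (−0.025) and T cell regulation (−0.369) at 10 days, granule (0.127) and neutrophil and mast cell (−0.548) at 12 weeks, and oxidative phosphorylation from 10 days to 12 weeks (0.288) and from 4 to 12 weeks (0.62), with medians given relative to all genes. It turned the median alone, and ended the call, of endoplasmic reticulum stress (0.091) and oxidative stress (0.021) at 12 weeks, oxidative phosphorylation at 4 weeks (−0.048), and T cell regulation (−0.155) and genes low in mature beta cells (0.079) from 4 to 12 weeks. It turned the median alone, and gave a call, of the neutrophil and mast cell list at 10 days (−0.555) and the T cell list at 4 weeks (0.113) and from 10 days to 4 weeks (0.219). Against 0, and not relative to all genes, it also turned Tie1 (0.06), Foxm1 (0.09), H2-K1 (0.07) and C1qbp (0.09) at 10 days and, at 12 weeks, Prss2 (0.99), Gcg (0.93), Gpx4 (0.65), Clock (0.41), Gad1 (0.06), Vamp2 (0.32), Cry2 (0.09), Resp18 (0.47), G6pc2 (0.37), Calr (0.27), Prlr (0.1), Reg1 (0.33), Ins1 (0.16), Dnajb9 (0.02) and Creld2 (0). Other than Prss2, Gcg and Gpx4, these genes still lay below the median of all genes under it. The share of genes lower at all ages in the 28 to 40 Mb part of chromosome 17 minus the rest turned from −0.59 percentage points to 1.12 with 2-fold calls and 1.49 with median centring. The T and B cell relation at 12 weeks lost its threshold with medians (0.95), with the processed signals (0.92) and with list means centred on the slide (0.98), where the few permutations within slides raise the p. The replicate numbers shared by the ages do not pair the mice, with 7 of 18 correlations of deviations above 0.1 (−0.32 to 0.61) and 2 of 18 arrays matching their own number best, and the replicate block called 9668, 9704, 7258, 9516, 8248 and 8046 genes and 717, 504, 637, 1650, 1589 and 1126 2-fold. Signal over background limits dim genes, which have only a bound where no array of an age measured them in 1 channel, and an uncertain value where few arrays did.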

Other observations

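The test of the type I interferon list against the Reg family in this part was chosen after the values were seen.

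Clock genes were lower in the NOD islets at 12 weeks, 6 of 13 with 0 higher (7 and 0 adjusted over the list alone; camera adjusted p = 0.00643, and adjusted p = 0.509 with an estimated correlation), with the clock output gene Dbp at −1.14 ± 0.20 and Nr1d2, a repressor of the clock loop, at −1.28 ± 0.44 (SD, n = 6, negative in 6 of 6 arrays), a call that median centring ended (−0.408, adjusted p = 0.0778), as it did those of Dbp (−0.04, adjusted p = 0.852) and Nr1d2 (−0.31, adjusted p = 0.161). At 10 days 5 of 13 were higher and 4 lower, and at 4 weeks 2 and 3 (the same counts adjusted over the list alone). Adipocyte genes rose relative to the pool from 10 days to 4 weeks in 7 of 8 and fell in 1 (the same counts adjusted over the list alone; adjusted p = 1.75e-05, and adjusted p = 0.436 with an estimated correlation). At 4 weeks only 4 of the 8 were well above background on at least 3 of 6 arrays in each channel, and at 10 days 8 in the pool and 5 in NOD, so that the size of the change is limited by the floor. That call ended with the strict filter on dim probes (adjusted p = 0.299). At 12 weeks 4 adipocyte genes were lower and 0 higher (also adjusted over the list alone; adjusted p = 0.0163, and adjusted p = 0.509 with an estimated correlation; strict filter 0.936), with the adipose complement factor Cfd at least 3.77-fold lower.

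Genes of Schwann cells, the glia that wrap islets, rose from 10 days to 4 weeks in 5 of 6 (also adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.52 with an estimated correlation; 0.0706 with slide as a block). They were not called at a single age, where 3 of 6 were lower at 10 days (adjusted p = 0.063), 4 higher at 4 weeks (0.0754) and 3 higher at 12 weeks (0.127), with the same counts adjusted over the list alone. Some alternatives called this list at a single age, such as the mean of a gene's probes at 10 days (0.0457) and the processed signals at 4 weeks (0.0427) and 12 weeks (0.0355). The red blood cell list had 4 of 5 genes higher at 4 weeks (also adjusted over the list alone; adjusted p = 0.119) and 2 lower at 12 weeks (3 adjusted over the list alone; 0.0615), and 4 of 5 fell from 4 to 12 weeks (also adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.518 with an estimated correlation; 0.0562 with no filter on dim probes). Some alternatives called it at a single age, among them median centring at 4 weeks (0.0352) and 12 weeks (0.0169). The lymphoid organisation list had 10 of 20 genes higher and 4 lower at 12 weeks (adjusted p = 0.165), and the immediate early and heat shock list 10 of 17 lower and 5 higher at 10 days (0.169) and 10 lower and 2 higher at 4 weeks (0.063), all with the same counts adjusted over the list alone. No filter called the former at 12 weeks (0.0407), and several alternatives called the latter at 4 weeks, such as the processed signals (0.0293). The neutrophil and mast cell list had 4 of 8 genes higher at 4 weeks (3 adjusted over the list alone; adjusted p = 0.1, and 0.00258 under median centring).

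The type I interferon list mean of the 4-week mice was −0.14, 0.86, −0.50, 1.98, −0.58 and 0.72 for replicates 1 to 6, and the Reg family mean of the same mice 1.74, 2.24, −1.44, 2.32, −2.05 and 1.15. A hypothesis from these values is that both lists may rise together between mice at 4 weeks. Pearson's r was 0.79 over the 6 mice (exact permutation p = 0.0583, adjusted p = 0.175 over the 3 ages), Spearman's rho was 0.94 (exact permutation p = 0.0167, adjusted p = 0.0501), and r was 0.73 without the 2 mice farthest from the median. At 10 days r was 0.52 (exact permutation p = 0.274), and −0.53 without the 2 farthest mice, and at 12 weeks −0.48 (exact permutation p = 0.356). The relation was thus not past the threshold at any age and stays open.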
